A study of Aedes aegypti with 6 samples.

How the data were processed

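RNA from testes of early male pupae of the yellow fever mosquito, Aedes aegypti, was hybridised to 6 one-colour NimbleGen expression arrays, 3 for the meiotic drive strain T37 and 3 for the non-driving strain RED. A one-colour array carries a single labelled sample, here marked with Cy3, so that the brightness of a feature reports the abundance of its transcript in that sample. Per the labels' protocols, males of both strains were reared at 26°C and 80% humidity with 16 h of light and 8 h of dark, total RNA was extracted with Trizol, DNA was digested, and NimbleGen did the labelling.

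The deposited table holds 1 intensity per transcript and array on a linear scale, and per the submitters' processing notes the arrays were processed with RMA, which corrects background, makes the arrays' probe distributions alike and summarises several probes into 1 value. The version of RMA, the array design, the probe sequences, the annotation release and the genome build are not given in the sources used here. The deposited intensities ran from 7.70 to 64205 and had medians between 1836 and 1985 on the 6 arrays, so they were neither on a log scale nor centred per gene. Because RMA pulls the arrays' distributions together, a shift of all transcripts in 1 strain would not be seen. No detection calls or control features were used here, so a low intensity could not be told from background.

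The table has 13471 transcripts of 12813 genes, named by identifiers of the AAEL series. Of these genes, 12307 have 1 transcript and 506 have several, up to 19. The files do not pair these identifiers with gene names, and 0 of the identifiers were found in the reference table of 19623 genes (assembly AaegL5.0), which gives other identifiers. Gene functions and positions were therefore not used here. For this reason the planned tests of 26 gene lists and of chromosome 1 were not run, and the rule for named genes, which asked for the 3 largest changes in each direction among genes past the test with no overlap between the strains' arrays, was kept to 2 in each direction.

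Samples were grouped by the strain in their titles. The free-text descriptions of the RED samples also count them among T37 replicates, against their titles, source names and strain labels, which all give RED. Each description says that replicates came from separately extracted testes. The number of males behind each extract is not given in the sources used here. All 6 columns of the table were matched to a sample by accession.

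Intensities were converted to log2 with no pseudocount, since every value was above 1, and transcripts of a gene were averaged on that scale. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 6 arrays, two-sided, no covariate, no filter on dim genes), with Benjamini-Hochberg adjustment over the 12813 genes and an adjusted p under 0.05 as the threshold. A second count asked for at least a 2-fold difference as well. Differences are T37 minus RED throughout, and intervals are 95% confidence intervals from the moderated fit. A permutation test of a single gene with 3 arrays against 3 cannot go below p = 0.1, so single genes were tested only within the model fitted across all genes. On arrays the number of replicates limits the precision. The procedure was tested on simulated data with the means of these genes and 200 changed genes among the 12813. Replicate spreads were shuffled over the genes and the noise was drawn independently. The procedure found 9 of 100 genes changed by 1 on the log2 scale and 53 of 100 changed by 2, with 4 false calls.

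The alternatives fixed before the data were examined were leaving out each array, a block for the replicate number, quantile normalisation, cyclic loess and median centring of the deposited values, removal of the dimmest 25% or 50% of the genes, an intensity trend or a robust prior in eBayes, array weights, transcripts tested singly, and a test against a 1.2-fold minimum. A further 3 were added after the data were seen: leaving out the third replicate of both strains, each array's 5th percentile as a covariate, and raising values under that percentile to it. The replicate numbers did not pair the arrays: the deviations of same-numbered arrays from their strain means correlated at -0.25, -0.16 and -0.17 across genes for replicates 1, 2 and 3. Deviations of differently numbered arrays correlated at -0.43 to 0.46, highest for T37 replicate 3 with RED replicate 1. The strains' arrays thus shared structure that the numbers did not capture and that the comparison took no account of.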

Results

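Meiotic drive is the transmission of a chromosome to more than its share of the gametes, and in Aedes aegypti the known driver is linked to the male-determining locus and gives an excess of sons. The comparison asked how gene expression in testes at the time of spermatogenesis differs between a strain that carries the drive, T37, and a strain without it, RED. Expression of 12813 genes was measured on 3 arrays of each strain, each from a separate extract of pupal testes. Median intensities were close on all arrays, at 1896, 1967 and 1887 for T37 replicates 1, 2 and 3 and at 1836, 1862 and 1985 for RED replicates 1, 2 and 3.

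The arrays of a strain were not equally alike. Across genes, which are not independent replicates, log2 intensities of T37 replicates 1 and 2 correlated at r = 0.983, and T37 replicate 3 correlated with them at 0.948 and 0.958. RED replicates 1 and 2 correlated at 0.974. RED replicate 3 stood apart, with r = 0.874 and 0.891 to RED replicates 1 and 2. Its r was 0.889, 0.908 and 0.900 to T37 replicates 1, 2 and 3. All of these were below the 0.940 between T37 replicate 1 and RED replicate 2. By median absolute log2 difference, however, it was nearest to RED replicate 1 (0.462), followed by T37 replicate 3 (0.485) and RED replicate 2 (0.496). The first principal component, with 42.7% of the variance, did not separate the strains, since RED replicate 3 scored -57.4 and the other RED arrays 63.5 and 42.3, with T37 between -33.3 and 7.19. On the second, with 36.9% of the variance, all T37 arrays had positive scores (13.0 to 47.8) and all RED arrays negative ones (-69.4 to -5.81). The median SD between replicates was 0.26 on the log2 scale in T37 and 0.35 in RED, and 67.3% of genes had the larger SD in RED. Without replicate 3 of the strain these medians were 0.12 in T37 and 0.22 in RED, over 2 arrays each. A median SD over 2 arrays tends to be lower than over 3, and no other array was left out for comparison. How much of the fall is due to replicate 3 is therefore not shown.

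**Figure D1:**
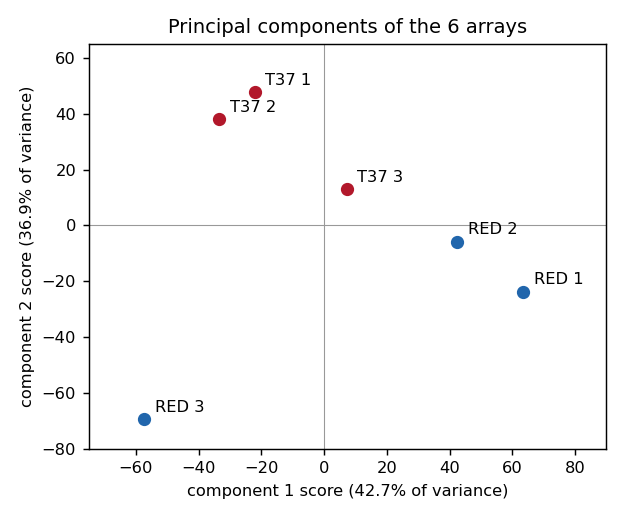
Scores of the 6 arrays on the first and second principal components of log2 intensity over 12813 genes; each point is 1 array, coloured by strain (T37 red, RED blue) and labelled with its replicate number. The second component places the T37 arrays above 0 and the RED arrays below it, while RED replicate 3 lies far from the other RED arrays on the first.

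Testes of the drive strain differed from those of the non-driving strain in 580 genes, 4.53% of those measured, by limma at an adjusted p under 0.05. Of these, 312 were higher and 268 were lower in T37. The median called gene was 2.89-fold higher or 2.87-fold lower, with an interquartile range of 2.28-fold to 3.91-fold for those higher and of 2.34-fold to 4.0-fold for those lower. These sizes describe only genes that passed, and the smallest difference that passed was 0.75 on the log2 scale. At least a 2-fold difference was found for 529 of the called genes, of which 287 were higher and 242 lower in T37. At least 4-fold differences numbered 77 higher and 67 lower, 8-fold differences 17 and 14, and 16-fold differences 4 and 3. The share of called genes that were higher in T37, 53.8%, moved to either side of even with the genes and arrays used: it was 63.9% without the dimmest 50% of genes and 42.8% without replicate 3 of both strains.

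On the deposited values, the largest rises in T37 were in AAEL002664 and AAEL007339. AAEL002664 had a log2 intensity of 10.16 ± 0.06 (SD, n = 3) in T37 and 3.81 ± 0.23 (SD, n = 3) in RED, a difference of 6.35 (SE 0.18, 95% interval 5.91 to 6.80; limma adjusted p = 0.00033), or 81.8-fold. On the deposited scale its intensity was 1143 ± 45.8 (SD, n = 3) against 14.1 ± 2.33 (SD, n = 3). AAEL007339 stood at 10.63 ± 0.25 (SD, n = 3) in T37 and 4.62 ± 0.24 (SD, n = 3) in RED, a difference of 6.01 (SE 0.22; limma adjusted p = 0.00065), or 64.6-fold. In RED both genes were among the dimmest on every array, at or below percentile 0.234 for AAEL002664 and percentile 0.593 for AAEL007339, whereas in T37 they lay at percentiles 39.2 to 49.1. Their folds thus rest on the darkest values of the arrays. With every value under an array's 5th percentile raised to it, the differences were 2.98 and 3.46 on the log2 scale, still past the test but ranked 15 and 7 among the 319 genes then called higher.

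The largest falls in T37 were in AAEL002331 and AAEL005063, which also ranked 1 and 2 with dim values raised. AAEL002331 had a log2 intensity of 6.15 ± 0.47 (SD, n = 3) in T37 and 12.44 ± 0.18 (SD, n = 3) in RED, a difference of -6.29 (SE 0.27, 95% interval -6.96 to -5.63; limma adjusted p = 0.0012), or 78.5-fold lower. It was the only gene that lay under the 5th percentile on all arrays of one strain and above the median on all arrays of the other. With dim values raised to the 5th percentile its difference was -5.34, still past the test, so its fold too rests on values at the dark end of the T37 arrays. AAEL005063 stood at 7.24 ± 0.11 (SD, n = 3) in T37 and 12.07 ± 0.35 (SD, n = 3) in RED, a difference of -4.82 (SE 0.22; limma adjusted p = 0.0012), or 28.3-fold lower. Its T37 values, at percentiles 4.16 to 7.54, also lay at the dark end of the arrays, and with dim values raised the difference was -4.78. Both were bright in RED, at percentiles 64.3 to 76.8.

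**Figure D2:**
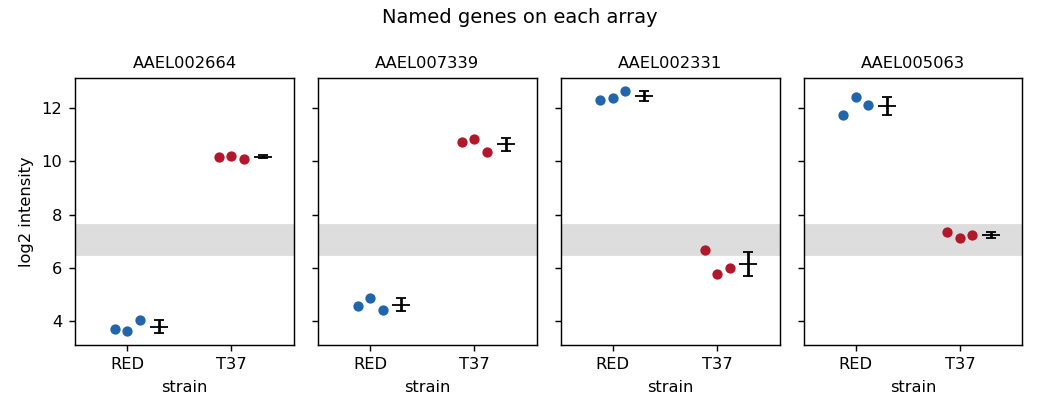
Log2 intensity of the 4 named genes, the 2 largest called rises and the 2 largest called falls in T37, 1 point per array (RED blue, T37 red), with the mean ± SD of the 3 arrays in black beside them; the grey band spans the 5th percentiles of the 6 arrays (6.47 to 7.61). The RED arrays of AAEL002664 and AAEL007339 and the T37 arrays of AAEL002331 lie near or below the band, far from the other strain's arrays.

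Genes of middle level were called most often. By deciles of mean log2 intensity, 7.10% of the genes were called in decile 4 (9.53 to 10.18) and 6.79% in decile 5, against 3.04% in decile 1, the dimmest, and 1.01% in decile 10. Among called genes in decile 1, 12 were higher and 27 were lower in T37, and in decile 10 there were 11 higher and 2 lower. The median log2 difference over all genes also moved with level, from -0.23 in decile 1 to 0.11 in decile 8, so the tendency of dim genes toward RED was not limited to called genes. That tendency depended on the scaling: after cyclic loess the median of decile 1 was 0.05, with 31 called genes higher and 17 lower in T37, whereas after quantile normalisation it was -0.17, with 25 higher and 29 lower. Of the called genes, 9 were under the 5th percentile on all RED arrays and 18 on all T37 arrays.

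**Figure D3:**
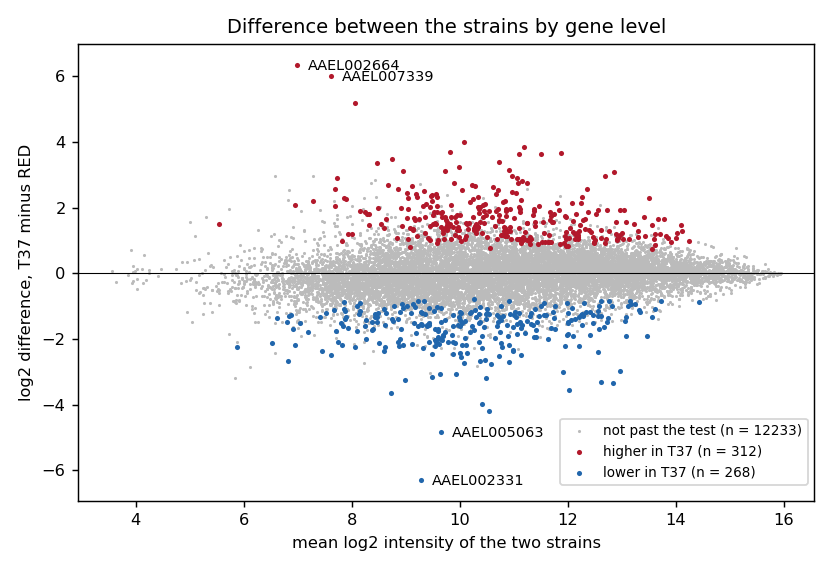
Log2 difference (T37 minus RED) against mean log2 intensity for 12813 genes, 1 point per gene; red points were higher and blue points lower in T37 at an adjusted p under 0.05 (limma), and grey points did not pass. Called genes occur on both sides at most levels, with the 4 named genes at the extremes.

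All 580 called genes had strain groups that did not overlap. Over all genes, the arrays of the strains did not overlap for 3681, or 28.7%, where chance gives 10%, with T37 above RED in 1967 and below it in 1714. At an unadjusted p under 0.05, limma found 2914 genes, against 641 that chance would give. Both chance figures, 10% and 641, assume that the arrays share no structure across genes beside the strain. Equal splits of the same arrays that mix the strains gave 2343 and 1636 genes at that threshold at most, and otherwise 43 to 619. The excess over these chance figures therefore cannot be put down to the strain alone. In the simulation the test recovered 9% of genes changed 2-fold and 53% of those changed 4-fold. That simulation held 200 changed genes, fewer than the 580 called here, and its spreads were shuffled over the genes. With more changed genes the adjusted threshold is looser, so these rates need not hold for this comparison. The test can still miss changed genes, and a gene outside the 580 is not shown to be alike in the strains.

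The number of called genes depended on single arrays. It was 15 without T37 replicate 1, 10 without T37 replicate 2, 313 without T37 replicate 3, 83 without RED replicate 1, 37 without RED replicate 2, and 957 without RED replicate 3, the array that stood apart. Of the 580 genes, 9 passed the test in all 6 of these fits, with the 4 named genes among them. Without the third replicates of both strains, 4221 genes were called, the 580 among them, with 1807 higher and 2414 lower in T37.

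**Figure D4:**
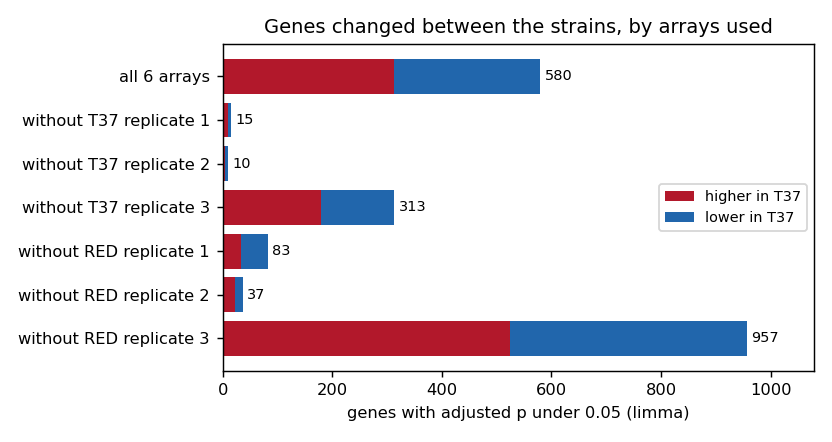
Number of genes with an adjusted p under 0.05 (limma), as bars from 0 split into genes higher (red) and lower (blue) in T37, with all 6 arrays and with each array left out in turn. The count is 580 with all arrays and ranges from 10 to 957 when 1 array is left out.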

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

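The 580 called genes (312 higher, 268 lower, 529 at least 2-fold) stayed within 1.5 times of their number under quantile normalisation, median centring, cyclic loess, removal of the dimmest 25%, an intensity trend, a robust prior, transcripts tested singly and raised dim values (528 to 723 genes). Leaving out 1 array gave 10 to 957 genes, 5 to 524 higher, 5 to 433 lower and 10 to 867 at least 2-fold. These fits have fewer arrays and so fewer degrees of freedom; why T37 replicates 1 and 2 matter most was not tested. With the replicate number as a block, limma called 0 genes (0 higher, 0 lower, 0 at least 2-fold), with 2467 at an unadjusted p under 0.05 and a smallest adjusted p of 0.051. The numbers do not pair the arrays: in deviations from the strain means, no array correlated best with its own number in the other strain. The block leaves every difference as it was by construction while taking degrees of freedom. Array weights, from 0.21 for RED replicate 3 to 4.71 for T37 replicate 2, gave 3841 genes (1985 higher, 1856 lower, 1962 at least 2-fold), and the test against a 1.2-fold minimum gave 279. Without the dimmest 50% of genes, 292 genes passed with at least 2-fold, since 250 of the 580 were left to test, and 63.9% of calls were higher in T37 against 53.8%. Among the alternatives added after the data were seen, leaving out replicate 3 of both strains gave 4221 (1807 higher, 2414 lower, 2787 at least 2-fold) and the 5th percentile as a covariate 1529 (799 higher, 730 lower, 975 at least 2-fold); the cause of these rises was not tested. The 4 named genes kept their side of the threshold in 66 of 70 values; the exceptions were the 4 under the block (adjusted p 0.051 to 0.077), and adjusted p elsewhere ranged up to 0.029. The planned gene list and chromosome tests were not run, and no value is given for the dimmer genes under the filters that remove them.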

Other observations

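The tests of transcripts and of the first component, the background covariate and the reading of cyclic loess and of raised dim values as tests of the called genes were chosen after the data or the counts of called genes were seen. One gene showed unequal differences in its transcripts. Among the 506 genes with several transcripts, limma's diffSplice (Simes-adjusted) found 1 whose transcripts differed between strains at an adjusted p under 0.05. At an unadjusted p under 0.05 it found 24, about as many as chance would give. In this gene, AAEL014945, transcript RB rose in T37, at 11.52 ± 0.17 (SD, n = 3) against 9.002 ± 0.61 (SD, n = 3) in RED, a 5.74-fold difference (limma adjusted p = 0.019 over all transcripts). Transcript RA stood at 6.83 ± 0.19 (SD, n = 3) in T37 against 8.15 ± 0.28 (SD, n = 3) in RED (limma adjusted p = 0.032), but it lay under the 5th percentile on all 3 T37 arrays, and with dim values raised to that percentile its difference of -1.04 no longer passed (limma adjusted p = 0.058). The gap between their differences was 3.84 on the log2 scale (limma adjusted p = 0.0010); it was 3.56 with dim values raised, stayed past the threshold in 12 of 13 alternatives and reached an adjusted p of 0.057 with the replicate block. Whether the gap reflects use of another transcript or a sequence difference under 1 set of probes was not tested.

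The main pattern is the 580 genes called between the strains. A candidate explanation is a level-dependent difference left between the arrays. After cyclic loess, 91.6% of the 580 (531 genes) were still called in the same direction. Cyclic loess moved other genes by a median of 0.096 on the log2 scale and called genes by 0.093, while the smallest called difference was 0.75. The level-dependent differences it removes were thus mostly small beside the called ones, and the survival of most calls says little more. With values under the 5th percentile raised to it, 96.6% (560 genes) were still called in the same direction, so values under that percentile do not account for most of the calls. Raising them leaves genes above that percentile as they were. Of the called genes, only 9 lay under it on all RED arrays and 18 on all T37 arrays. For the other called genes this says little about dim values. The background of each array above that level stays open: with the 5th percentile as a covariate 100% of the 580 kept their sign and at least 50% of their size, but the strain means of that percentile were close (7.10 ± 0.23 in T37 and 7.18 ± 0.61 in RED, SD, n = 3 each), so the covariate could hardly have moved any difference. In the splits of the 6 arrays into 3 and 3, 1 of 10, the real one, gave 580 genes and the highest of the other splits gave 0; with 10 splits the share cannot fall under 0.05. Sequence differences between the strains under the probes, other tissue in the dissections, a difference in pupal age and the drive itself stay open and untested. So do expression differences between the strains that have nothing to do with the drive. With 1 strain of each kind, these cannot be told apart from the drive. One other split, T37 replicates 1 and 2 with RED replicate 3 against the rest, came near in genes at an unadjusted p under 0.05 (2343, against 2914 for the strains), which points to a structure of the arrays beside the strain.

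That structure followed the dim end of the arrays. The 5th percentile of log2 intensity ran from 6.47 on RED replicate 3 to 7.61 on RED replicate 1. Over the 6 arrays it correlated with the score on the first component (Pearson r = 0.95, exact permutation p = 0.0069, and Spearman rho = 0.943, exact permutation p = 0.017). Both quantities come from the same log2 intensities, and this relation was not planned. The correlation thus describes the structure, and its p-values are no independent support. Without the 2 arrays farthest from the median, RED replicates 3 and 1, r was 0.931 over 4 arrays. Within a strain there were only 3 arrays, too few for a test. Whether RED replicate 3 is a T37 sample under a RED label was tested on the 957 genes called without it. On that array 70.2% of them (672 genes) lay nearer to the other RED arrays than to T37. This was short of the 80% set beforehand to exclude such a label and above the 50% set to accept it, so by that rule it stays open. Other values went both ways. On the second component, which separated the strains, the array scored -69.4, on the RED side. Its r, however, was 0.889, 0.908 and 0.900 to T37 replicates 1, 2 and 3, against 0.874 and 0.891 to RED replicates 1 and 2. The first component, where the array scored -57.4, did not separate the strains and so gives no side. The 4 named genes, which also passed without this array, had values on it near those of the other RED arrays, but they were picked with it among the RED arrays. No slide or scan date was used here, and no biological explanation of this structure was tested.

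It was asked as a hypothesis whether called genes sit side by side, taking consecutive identifier numbers as a rough stand-in for neighbouring genes, which the files do not establish. Of 10675 pairs of consecutive identifiers, 17 were called in the same direction, against a median of 11 and a 95th percentile of 17 in 10000 shuffles of the calls among genes of similar level (one-sided permutation p = 0.053). The most calls in 20 consecutive measured identifiers was 6, against a shuffled median of 5 (one-sided permutation p = 0.44). Chance placement could account for both counts, so the hypothesis was not borne out.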
